A study of Mus musculus with 6 samples.

How the data were processed

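RNA was measured in peritoneal macrophages sorted from 6 female Ldlr-/- mice, 3 per genotype, as described in the series' design text and the labels' protocols. Strand-specific poly(A)+ libraries were made from at least 150 ng of RNA and planned at 20 M paired-end reads of 100 bp each, on an Element AVITI instrument, per the labels' protocols. Per the submitters' processing notes, the tools were Salmon 1.10.2, MultiQC and DESeq2 1.40.0, and the builds were GRCm39 and mm10, with no role given for either. The count table deposited by the authors holds estimated counts per Ensembl gene, 55822 genes in all, of which 23.9% of values were not whole numbers. Whether the estimated counts were scaled by transcript length is not given in the sources used here. The other table deposited by the authors holds log2 values from a regularized log transform, per the file headers and names, for 32961 entries in which 321 identifiers were repeated. It also pairs gene identifiers with symbols.

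The columns of both tables carry the group name and the numbers 3 to 5, while the labels number the mice of each group 1 to 3. Columns were therefore assigned to a group but not to a numbered mouse, and libraries are named here by their column header, so that library Ctl4 is a Ctl library whose number is not a number of the labels. Every column belonged to 1 of the 2 groups. Symbols came from the deposited table for 32640 identifiers and from the GENCODE M21 names for another 19540, and 3642 had none. The reference annotation used here is of an older build than the identifiers of the count table, so no coordinates are given and it served for names and for which genes neighbour each other on a chromosome.

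Estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr at its default minimum count of 10, which left 13036 genes, and libraries were scaled by TMM. LipaTg was compared with Ctl with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are LipaTg over Ctl. Their standard error (SE) is the log2 fold change divided by the square root of F, and levels are TMM-scaled CPM, the depth-scaled counts of the edgeR function cpm, given as mean ± SD of 3 libraries. Gene lists, 31 in number with 613 entries, were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. For each list the members past the threshold were counted after adjustment over all genes tested and after adjustment over the list alone. Chance puts the 3 libraries of one group all above or all below the other 3 for 10% of genes.

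The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Lipa, Lyz2, Lyz1, Gt(ROSA)26Sor and Ldlr always. It added up to 10 genes per direction with the largest change among those past the threshold with a mean of at least 1 CPM, separated groups and a regular symbol. For each list it took up to 4 members past the threshold, or, where a list passed camera with no such member, its 2 members with the smallest p. For each list of markers of another cell type it took the most abundant member. In all 36 genes were named by the rule, and others are said to have been chosen after their values were seen.

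The alternatives were RLE factors, library totals, DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of at least 50), the first surrogate variable from sva 3.50.0 as a covariate, each library left out in turn, a 1.5-fold minimum, and an adjusted p under 0.1. Thinning all libraries to the smallest total was added after the depths of the libraries were seen, and after the data were seen so were lists for plasma cells, class I and class II genes, DNA replication, mitosis, ribosomal proteins and guanylate-binding proteins. The planned block for the labels' replicate number was not used here, since the columns do not carry that number, and a block on the number in the column names was added after the data were seen.

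The edgeR steps were tested on simulated data drawn from the means and totals of these libraries for the LipaTg against Ctl comparison over 13036 genes. Of 50 genes changed at each size, the test recovered 4% at 1.25-fold, 50% at 1.5-fold, 66% at 2-fold and 86% at 4-fold, and it called 9 of 12812 unchanged genes. Over all 200 changed genes edgeR recovered 103, DESeq2 112 and limma-voom 98. Of the unchanged genes DESeq2 called 19 and limma-voom 10. The simulation drew each gene independently, while many genes of the real libraries moved together, so these rates may not carry over to the real data. A count of 3 corresponds to between 0.126 and 0.157 CPM in these libraries. Gene-level counts cannot divide reads between near-identical genes such as Lyz1 and Lyz2, so these values depend on how Salmon assigned shared reads.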

Results

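Peritoneal macrophages were profiled by RNA-seq in female Ldlr-/- mice, which lack the LDL receptor and become hypercholesterolaemic on a fat-rich diet, after 16 weeks of Western diet. The series asked what overexpression of Lipa, the gene for lysosomal acid lipase, in myeloid cells does to the macrophage transcriptome. All mice carried 1 copy of a Lipa transgene in the Rosa26 locus. In the 3 LipaTg mice a Cre recombinase inserted in the lysozyme gene Lyz2 (LysMCre) switched it on together with an eGFP marker, and the 3 Ctl littermates had no Cre. Viable macrophages were sorted without culture, by CD45 and F4/80 in Ctl mice and by CD45, F4/80 and eGFP in LipaTg mice, so the sorting gate differed along with the genotype. Estimated counts totalled 21613087 in library Ctl3, 19272334 in Ctl4 and 19113912 in Ctl5, and 23636188 in LipaTg3, 23843173 in LipaTg4 and 22034550 in LipaTg5. Each LipaTg library was thus deeper than each Ctl library. No pair of libraries within a group was alike within sampling noise, with a chi-square per degree of freedom of 11.7 to 24.6. The first principal component held 32.9% of the variance, and on it library Ctl3 (-1.74) lay between the other Ctl libraries (22.3 and 31.7) and the LipaTg libraries (-30.4 to -10.7).

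Lipa rose in LipaTg macrophages in all 3 libraries, from 416 ± 49.4 CPM in Ctl to 1145 ± 43.3 CPM (SD, n = 3 each), which is 2.75-fold. The 8 genes that changed between the genotypes included the gene that the transgene encodes, the transcript of the transgene's insertion locus and the lysozyme pair at the Cre locus. Lyz2, the macrophage lysozyme that holds the Cre insertion, fell to 45.1% of its Ctl level, from 42088 ± 1956 to 18971 ± 1551 CPM. Its neighbour Lyz1, the Paneth cell lysozyme with a near-identical sequence, rose 2.83-fold, from 842 ± 68.0 to 2386 ± 379 CPM. Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus, rose from 1.95 ± 0.666 to 8.22 ± 0.509 CPM.

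These changes were tested with edgeR's quasi-likelihood test over 13036 genes. The log2 fold change of Lipa (ENSMUSG00000024781) was 1.46 ± 0.0872 (SE), with an adjusted p of 4.38e-05 in edgeR. That of Lyz2 (ENSMUSG00000069516) was -1.15 ± 0.0786 with an edgeR adjusted p of 9.22e-05, and that of Lyz1 (ENSMUSG00000069515) was 1.502 ± 0.116 with an edgeR adjusted p of 0.00119. Gt(ROSA)26Sor (ENSMUSG00000086429) had 2.07 ± 0.234 and an edgeR adjusted p of 0.00766. Lyz1 and Lyz2 share reads, so the values of both are uncertain. Ldlr, disrupted in both groups, had 441 ± 15.8 CPM in Ctl and 429 ± 13.1 CPM in LipaTg, a log2 fold change of -0.04 ± 0.0640 that did not pass edgeR (adjusted p = 0.905).

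The other 4 changed genes were Il2rg, which rose, and Emb, Igkc and Itgb3, which fell. Il2rg, the common gamma chain shared by receptors of several interleukins, rose 1.52-fold, from 115 ± 8.89 to 176 ± 13.1 CPM. Emb, which encodes the membrane glycoprotein embigin, fell from 15.2 ± 2.62 to 6.17 ± 0.332 CPM. Igkc, the constant region of the immunoglobulin kappa light chain made by B lineage cells, fell from 49.6 ± 5.14 to 27.9 ± 2.70 CPM, and Itgb3, the integrin beta 3 subunit of the vitronectin receptor, fell from 57.9 ± 5.65 to 33.2 ± 4.24 CPM. Log2 fold changes were 0.61 ± 0.0830 for Il2rg (ENSMUSG00000031304; edgeR adjusted p = 0.0237), -1.30 ± 0.150 for Emb (ENSMUSG00000021728; edgeR adjusted p = 0.00766), -0.83 ± 0.103 for Igkc (ENSMUSG00000076609; edgeR adjusted p = 0.0125) and -0.80 ± 0.108 for Itgb3 (ENSMUSG00000020689; edgeR adjusted p = 0.0237). The call of Emb was lost without Ctl4 (edgeR adjusted p = 0.054) or Ctl5 (0.0501), those of Igkc and Itgb3 without Ctl4 (0.0611 and 0.112), Ctl5 (0.071 and 0.107) or LipaTg4 (0.064 for both), and that of Il2rg without Ctl4 (0.132), Ctl5 (0.151), LipaTg3 (0.0584) or LipaTg4 (0.097).

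**Figure D1:**
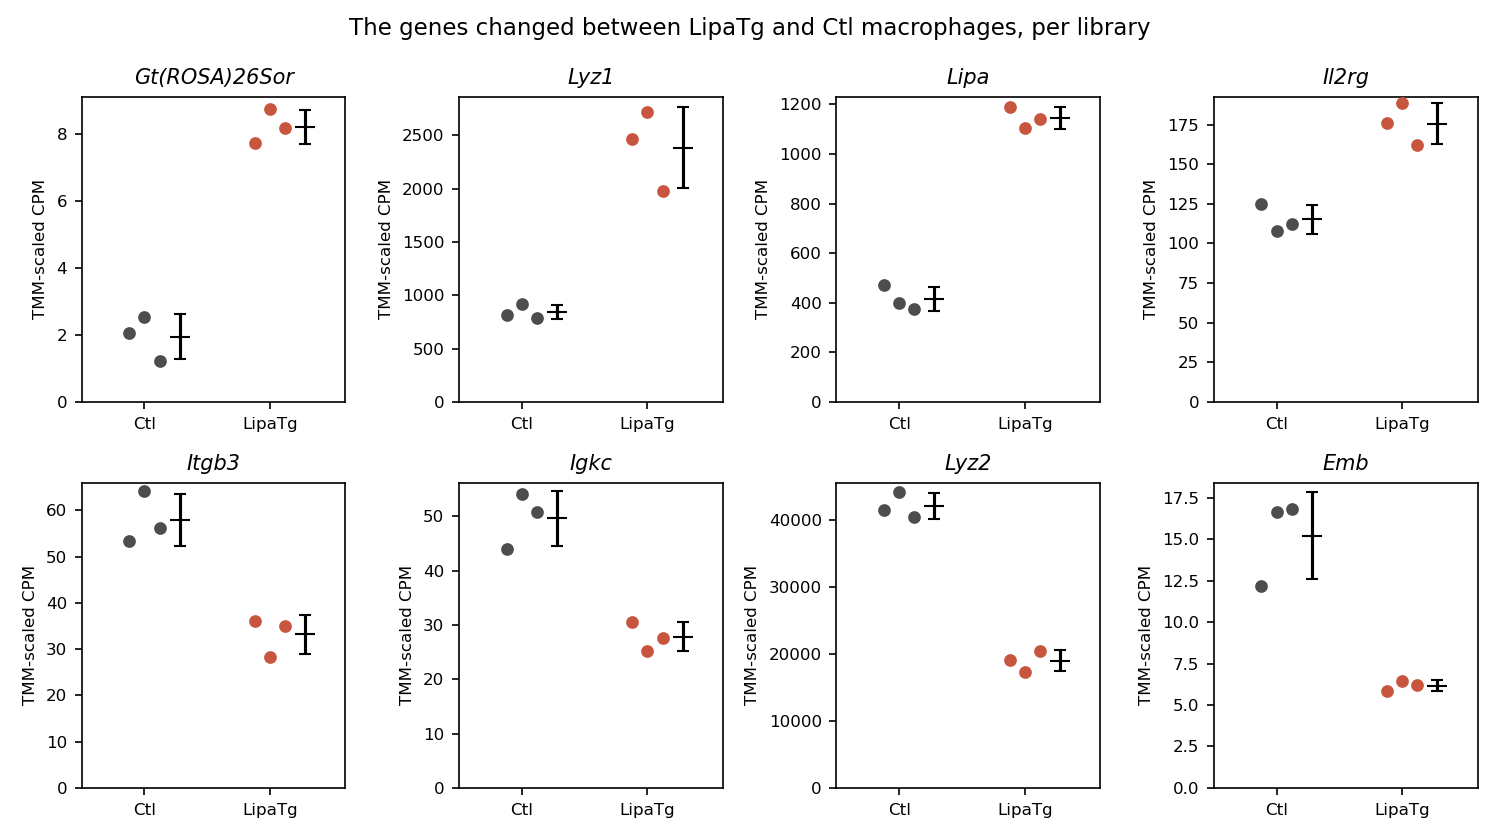
TMM-scaled CPM (vertical axes, each from 0) of the 8 changed genes in the 3 Ctl libraries (grey) and 3 LipaTg libraries (red), 1 point per library, with the mean and SD of each group beside the points. In every panel the groups are separated, and Lipa lies between 376.5 and 471 CPM in Ctl and between 1104 and 1190.3 CPM in LipaTg.

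Of the 13036 genes tested, 4 rose and 4 fell past an adjusted p of 0.05 in edgeR. At an unadjusted p under 0.05 there were 703 genes with a higher and 599 with a lower level in LipaTg, 1302 in all, where chance alone gives 652. Splits of the same libraries that mixed the genotypes gave 186 to 1226 such genes, so the excess over 652 is no count of genotype effects. The number of calls depended on the test and on single libraries. DESeq2 called 139 genes higher and 72 lower, among them all 8, while the edgeR count was 170 without library Ctl3, 33 without LipaTg3, 28 without LipaTg5 and 5 without Ctl4. In the simulated data DESeq2 called 19 unchanged genes and edgeR 9, so the added DESeq2 calls may hold more false ones.

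The cell cycle list rose in LipaTg macrophages by camera at the preset correlation only. All 24 measured members had higher means, with a median log2 fold change of 0.67, and camera gave the list an adjusted p of 2.08e-14. The call was lost with the correlation between genes estimated from the data (adjusted p = 0.615 with an estimated correlation) and with fry. By edgeR no member passed over all genes, 13 had an unadjusted p under 0.05, and 10 were past the threshold adjusted over the list alone, while DESeq2 called 10 over all genes and limma-voom called 0. Mcm7 and Mcm5, subunits of the helicase that opens DNA for replication, stood at 22.2 ± 2.22 against 37.3 ± 4.76 CPM and at 17.3 ± 3.33 against 35.0 ± 5.87 CPM (edgeR adjusted p = 0.0544 and 0.0957). Without library Ctl3 the median of the list was 1.05.

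Antigen presentation genes also rose as a list, 18 of 19 with a higher mean in LipaTg, with a median log2 fold change of 0.63 and a camera adjusted p of 2.52e-12 at the preset correlation (adjusted p = 0.615 with an estimated correlation). By edgeR 0 members passed over all genes, 14 had an unadjusted p under 0.05, all higher, and 12 passed adjusted over the list alone. DESeq2 called 8 and limma-voom 4 over all genes. H2-Eb1, a class II histocompatibility chain, stood at 43.6 ± 7.36 CPM in Ctl and 119 ± 28.3 CPM in LipaTg, and Cd74, the invariant chain that escorts class II molecules, at 185 ± 39.5 and 644 ± 175 CPM. Their log2 fold changes were 1.45 ± 0.203 and 1.80 ± 0.262, neither past edgeR over all genes (adjusted p = 0.137 and 0.161).

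Interferon response genes rose as a list too, with 26 of 28 members higher, a median log2 fold change of 0.41 and a camera adjusted p of 6.45e-12 at the preset correlation (adjusted p = 0.615 with an estimated correlation). Over all genes edgeR called 0 of them, DESeq2 6 and limma-voom 0, 20 had a higher and 1 a lower mean with an unadjusted edgeR p under 0.05, and 15 passed adjusted over the list alone. Ifit1 and Ifit2, antiviral proteins induced by interferon, had log2 fold changes of 0.73 ± 0.141 and 1.73 ± 0.350 (edgeR adjusted p = 0.139 and 0.161). The glycolysis list rose by a small margin (15 of 18 members higher, median 0.08, camera adjusted p = 0.0137, and adjusted p = 0.615 with an estimated correlation), and so did the apoptosis list (15 of 21 higher, median 0.14, camera adjusted p = 0.0137, and adjusted p = 0.615 with an estimated correlation). In neither did a member pass edgeR over all genes or adjusted over the list alone, with 5 and 4 members at an unadjusted p under 0.05 and 0 and 2 called by DESeq2. The glycolytic enzymes Gapdh and Pfkp had log2 fold changes of 0.20 ± 0.0655 and 0.23 ± 0.0796 (edgeR adjusted p = 0.310 and 0.336). Bak1, which permeabilises mitochondria in apoptosis, had 0.51 ± 0.125 and Cdkn1a, the cell cycle inhibitor p21, had 0.51 ± 0.140 (edgeR adjusted p = 0.192 and 0.247). The glycolysis call was lost without Ctl4 (camera adjusted p = 0.061), LipaTg3 (0.0608) or LipaTg4 (0.123), and the apoptosis call without Ctl4 (0.066). The glycolysis median was 0.14 without LipaTg5, and the apoptosis median was 0.09 without LipaTg4 and 0.21 without LipaTg5.

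Fatty acid oxidation genes fell as a list, with 23 of 24 members lower, a median log2 fold change of -0.10 and a camera adjusted p of 0.00123 (adjusted p = 0.615 with an estimated correlation). By edgeR 0 passed over all genes, 7 lower and 1 higher member had an unadjusted p under 0.05, and 2 passed adjusted over the list alone. DESeq2 called the same number, 2, and limma-voom 0. These were, in edgeR, Etfb, a subunit of the flavoprotein that takes electrons from acyl-CoA dehydrogenases, with -0.35 ± 0.0809, and Acaa2, the thiolase of mitochondrial beta-oxidation, with -0.40 ± 0.0981 (edgeR adjusted p over all genes = 0.161 and 0.192).

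The list of lipid-associated macrophage genes fell (9 of 14 lower, median -0.39, camera adjusted p = 0.0261, and adjusted p = 0.615 with an estimated correlation). Cd63, a tetraspanin of late endosomes, had -0.59 ± 0.102 and the apolipoprotein gene Apoc2 had -0.41 ± 0.0940 (edgeR adjusted p = 0.0971 and 0.161), the 2 members past the threshold adjusted over the list alone. The list of alternative activation genes fell with 13 of 16 members lower, a median of -0.13 and a camera adjusted p of 0.0459 (adjusted p = 0.615 with an estimated correlation). The 2 members past the threshold adjusted over the list alone were the C-type lectins Mgl2, with -0.87 ± 0.177, and Clec10a, with -0.69 ± 0.140 (edgeR adjusted p = 0.151 and 0.161). Over all genes edgeR called 0 members of either list, DESeq2 2 of each and limma-voom 0, and 5 and 3 members were lower, and 1 of each higher, at an unadjusted edgeR p under 0.05. The first of these calls was lost without Ctl3 (camera adjusted p = 0.164, median -0.25), Ctl4 (0.0716) or LipaTg5 (0.168), without a low-count filter (0.231, median -0.06) and with the stricter filter (0.0556, median -0.21), and the other without Ctl5 (0.541, with a median of 0.02, against -0.36 without LipaTg3) or LipaTg4 (0.123), with the surrogate variable (0.0612) and after thinning (0.0533).

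**Figure D2:**
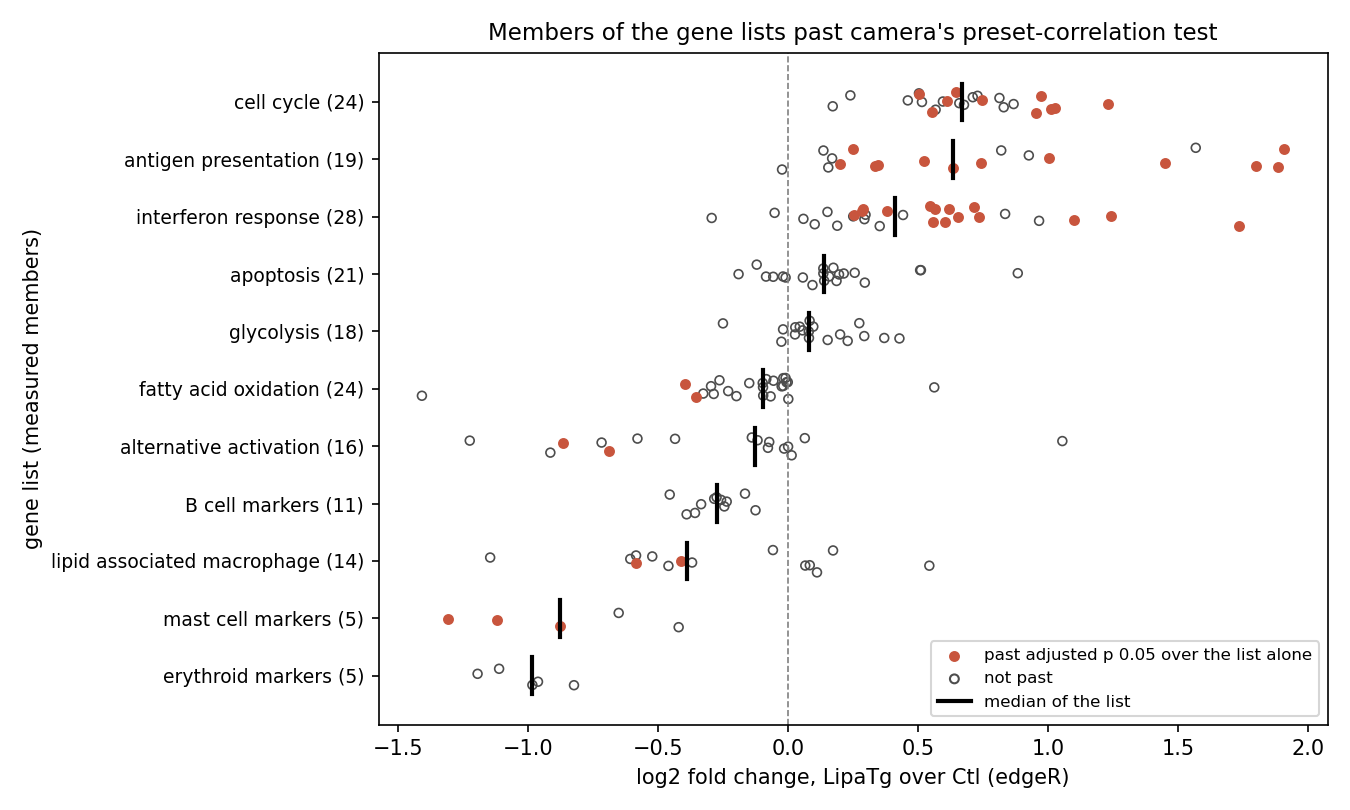
Log2 fold change, LipaTg over Ctl (horizontal axis), of each measured member of the 11 gene lists past camera at the preset correlation (vertical axis, number of members in brackets), 1 point per gene. Filled points passed edgeR adjusted over the list alone, open points did not, and the bar is the median, from 0.67 for cell cycle genes to -0.98 for erythroid markers.

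Of the 8 lists of markers of other cell types, most of which a gate on CD45 and F4/80 is meant to remove, 3 fell by camera at the preset correlation. Mast cell markers fell as a list (5 of 5 lower, median -0.88, camera adjusted p = 0.00149, and adjusted p = 0.615 with an estimated correlation), among them the proteases Mcpt4, at 5.91 ± 2.33 CPM in Ctl and 2.38 ± 0.858 CPM in LipaTg, and Tpsb2, at 4.89 ± 0.962 and 2.24 ± 0.872 CPM. B cell markers fell as a list (11 of 11 lower, median -0.28, camera adjusted p = 0.00149, and adjusted p = 0.615 with an estimated correlation). Ighm, their most abundant member, stood at 120.1 ± 30.2 and 87.5 ± 11.5 CPM (edgeR adjusted p = 0.507), and Cd79a, a signalling chain of the B cell receptor, had a log2 fold change of -0.24 ± 0.110 (edgeR adjusted p = 0.514). Erythroid markers fell as a list (5 of 5 lower, median -0.98, camera adjusted p = 0.00638, and adjusted p = 0.615 with an estimated correlation), with the globin genes Hbb-bs at 351 ± 75.5 and 198 ± 127 CPM and Hba-a2 at 203 ± 57.6 and 104 ± 71.6 CPM (edgeR adjusted p = 0.734 and 0.739). By edgeR no marker passed over all genes, 3 mast cell markers had an unadjusted p under 0.05 and passed adjusted over the list alone, and DESeq2 called 2 mast cell markers over all genes and no B cell or erythroid marker. The B cell call was lost without Ctl5 (camera adjusted p = 0.0972, median -0.14), and its median was -0.18 without LipaTg4. The erythroid call was lost without Ctl3 (0.085), and its median ran from -0.55 without LipaTg4 to -2.04 without LipaTg3, in which Hbb-bs stood at 339 CPM.

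Markers of T and NK cells (camera adjusted p = 0.0519), neutrophils (0.823), eosinophils (0.616), dendritic cells (0.552) and mesothelial cells and fibroblasts (0.797) did not pass. Their most abundant members were Il7r, at 1.22 ± 0.407 CPM in Ctl and 0.685 ± 0.583 CPM in LipaTg, Csf3r, at 265 ± 18.1 and 226 ± 22.6 CPM, Il5ra, at 1.74 ± 0.247 and 1.08 ± 0.249 CPM, Cd209a, at 42.3 ± 7.28 and 17.7 ± 5.39 CPM, and Msln, at 1.39 ± 0.365 and 1.53 ± 0.329 CPM. None of these 5 genes passed edgeR over all genes (adjusted p from 0.193 to 0.947). DESeq2 called Cd209a lower (log2 fold change -1.26, adjusted p = 3.69e-07) and put the dendritic cell list past camera (0.0333), lower (adjusted p = 0.734 with an estimated correlation). Only 2 of its 4 members were lower in edgeR, and its DESeq2 median was -0.06. The list of T and NK cells passed, lower, in 8 of 17 alternatives, with 0.000716 without LipaTg5 as the smallest adjusted p, but adjusted p = 0.615 with an estimated correlation and 0.42 with fry.

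Lists for the lysosome, autophagy, sterols and lipid uptake did not pass camera, unlike those above for fatty acid oxidation and lipid-associated macrophages. The lysosome list, 36 genes for hydrolases, membrane proteins and the proton pump, had a median log2 fold change of 0.01 and a camera adjusted p of 0.737. Autophagy genes (adjusted p = 0.832), cholesterol synthesis genes (0.962), targets of the sterol-sensing receptor LXR (0.823) and genes of lipid uptake and storage (0.239) did not pass either. Camera asks for a shift in one direction, and single members did move. Over all genes DESeq2 called 1 lysosome gene lower, 1 LXR target higher and 1 lower, and 1 gene of lipid uptake and storage lower, where edgeR called 0. Nor did lists for oxidative phosphorylation (0.539), inflammatory cytokines (0.239), efferocytosis and phagocytosis (0.473), large peritoneal macrophages (0.797), small peritoneal macrophages and monocytes (0.816), integrins and extracellular matrix (0.701), eicosanoids (0.469), antioxidant genes (0.91), endoplasmic reticulum stress (0.137) or immediate early genes of cell dissociation (0.0519). That last list, which reflects the handling of cells, had 15 of 18 members lower in LipaTg and passed in 10 of 18 alternatives, with 0.00622 in DESeq2 as the smallest adjusted p, but not with an estimated correlation (0.615). Single alternatives put the lists for inflammatory cytokines (0.0198 without Ctl3, higher, with a median of 0.30 against 0.08) and oxidative phosphorylation (0.0497 without LipaTg5, higher) past camera. The list for endoplasmic reticulum stress passed, lower, without Ctl3 (0.0198) and with library totals (0.0352). None of these lists passed with an estimated correlation (0.784, 0.909 and 0.615). Itgb3, listed under efferocytosis and under integrins, was the only member of any of the 31 lists past edgeR over all genes. For the lysosome, autophagy, cholesterol synthesis and neutrophil lists the median, the mean and the direction of the test differed in sign. Of the 31 lists, 11 passed camera at the preset correlation and 0 with the estimated correlation, where none had an unadjusted p under 0.05 either. By fry, which asks whether a list moves one way, 0 passed (smallest adjusted p = 0.276) and 5 had an unadjusted p under 0.05, and by its test for change in either direction 5 passed. These were the lists for eicosanoids (0.0039), integrins and extracellular matrix (0.0208), efferocytosis (0.0213), lipid-associated macrophages (0.0213) and antigen presentation (0.0465).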

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

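Thinning was chosen after the depths of the libraries were seen, and the block on the column number after all results were seen. The columns do not carry the labels' replicate numbers, so a replicate block could be fitted only on the column numbers 3 to 5, whose meaning is not given in the sources used here. Same-numbered libraries did not all deviate together from their group means (correlations -0.00736, 0.0467 and 0.102), and not every library correlated best with its own number. With this replicate block edgeR called 37 genes, 16 higher and 21 lower, among them all 8, and no gene or list past the threshold lost its call. The lists for endoplasmic reticulum stress, cell dissociation and T and NK cells gained one. Lipa, Lyz2 and Lyz1 passed in all 16 alternative fits, Lipa with log2 fold changes from 1.39 to 1.56. Gt(ROSA)26Sor passed in 15 and missed only with limma on the deposited log2 values, where all 5 lost genes had an adjusted p of 0.0563.

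The count of 8 changed genes moved to 13 with library totals, 211 with DESeq2, 13 with limma-voom, 4 with limma on the deposited log2 values (3 of them among the 8), 550 without a low-count filter, 85 with the surrogate variable, 22 at an adjusted p under 0.1, and 5 to 170 with 1 library left out. The 4 higher genes became 9 with library totals, 139 with DESeq2, 8 with limma-voom, 335 without the filter, 64 with the surrogate variable, and 3 to 126 with 1 library left out. The 4 lower genes became 72 with DESeq2, 1 with limma on the deposited log2 values, 215 without the filter, 21 with the surrogate variable, and 2 to 44 with 1 library left out. All 8 genes were among the calls of each fit over all 6 libraries except the one on the deposited log2 values. The 11 lists past camera became 0 with an estimated correlation and 0 with fry, and 10 to 14 in all others. The cause of these moves was not tested. Leaving out Ctl3, whose surrogate value of -0.667 was the most extreme, gave the count of 170.

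Genes whose sign turned were Ldlr (0.01518 with library totals) and Msln (-0.02842 to 0.3516 with 1 library left out, -0.02842 without Ctl5 and -0.01968 without LipaTg3), none past the threshold in any fit. Library totals moved the median log2 of all genes from -0.00586 to 0.0506, and their split of 9 higher to 4 lower stands against 4 to 4 with TMM. Depth limits genes near 0.157 CPM, where 3 counts are expected in the shallowest library.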

Other observations

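All tests in this part were chosen after the result was seen, except those on thinned libraries, on splits of the libraries, on genes around Lyz2 and on the share of abundant members of marker lists past edgeR, which were written before their results; the lists and families named next were picked after their values were seen.

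Class II genes had a larger median than class I genes, a difference that was not tested. All 7 class II genes had higher means in LipaTg, with a median log2 fold change of 1.57, and 6 passed edgeR adjusted over the list alone (0 over all genes, where DESeq2 called 6 and limma-voom 4, and 6 had an unadjusted p under 0.05). Camera's adjusted p of 6.99e-10 became 0.135 with an estimated correlation, while fry, adjusted over the 5 added lists, gave 0.038. H2-Ab1 stood at 57.8 CPM in Ctl and 217 CPM in LipaTg and H2-Aa at 69.5 and 257 CPM. Ciita, the activator of class II transcription, stood at 3.71 and 10.98 CPM (edgeR adjusted p = 0.519). Guanylate-binding proteins, GTPases induced by interferon gamma, went the same way, with 11 of 11 higher and a median of 1.08, though camera's p of 9.25e-10 became p = 0.102 with an estimated correlation. The 9 class I genes had a median of 0.35, and 6 of them also passed adjusted over the list alone (camera adjusted p = 5.44e-07, and 0.135 with an estimated correlation). Within the cell cycle list, 8 of 10 DNA replication genes and 0 of 14 mitosis genes passed edgeR adjusted over their own lists, yet the medians were 0.63 and 0.69, and the difference was not tested (with an estimated correlation, camera adjusted p = 0.135 and 0.211, and fry adjusted p = 0.038 and 0.118). The added plasma cell list had 6 of 7 members lower and a median of -0.46, with Mzb1 at 3.59 CPM in Ctl and 1.76 CPM in LipaTg. Its camera adjusted p of 0.0353 became 0.224 with an estimated correlation, and fry gave an adjusted p of 0.118.

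Cytoplasmic ribosomal protein genes had slightly lower levels in LipaTg, 80 of 81 of them, with a median log2 fold change of -0.20, which was -0.15 with library totals. In 72 of the 81 all 3 LipaTg libraries lay below all 3 Ctl libraries, where chance gives 10% over both directions for a single gene. These genes moved together and are not 81 separate trials, so the 10% is no measure for the family. None passed edgeR over all genes and 69 passed adjusted over the family alone, and camera's p of 3.77e-30 became p = 0.0655 with an estimated correlation of 0.454. Gm14288, a predicted gene, had the largest log2 fold change among genes under an adjusted p of 0.1, 4.95 ± 0.641 (edgeR adjusted p = 0.0997), with 0 to 0.642 CPM in the Ctl libraries and 6.64 to 14.4 CPM in the LipaTg libraries.

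With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split gave 8 changed genes, and the highest of the others gave 0, so that 1 split reached the real count. At an unadjusted p under 0.05 the real split gave 1302 genes and the others 186 to 1226. The highest of these was the split of Ctl3, LipaTg3 and LipaTg4 against the rest, and the next gave 838. Each of them exchanges 1 library per group with the real split, so differences between the genotypes carry into it. Whether a structure of the libraries beyond genotype adds to the 1226 was not tested.

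A different share of cell types after the eGFP gate could also produce changed genes. Any gene carried by large peritoneal macrophages would move with their share as their markers do, and the 95% bootstrap bounds of the median of these 20 markers lay within 0.137 of 0, which says nothing about genes carried by minor cell types, such as Igkc. The bootstrap resampled the members of a list and not the libraries, so all such bounds leave out variation between mice. Over the alternatives the median of these markers ran from -0.07914 to 0.02181. More cells of another type would have to raise its markers by at least the rise of Lipa, Lyz1 and Gt(ROSA)26Sor, but for B cells, mast cells, erythroid cells and small peritoneal macrophages with monocytes the upper bound was at most 0.208, below the lower 95% bound of each of these genes. Dendritic, T and NK cells, neutrophils, eosinophils and mesothelial cells had too few or too scarce markers for this bound and stay open. Their upper bounds, 0.371, -0.419, 0.609, 0.537 and 0.129 in that order, also lay below the lowest gene bound of 1.24. Lipa is also the gene that the transgene encodes, and Gt(ROSA)26Sor the transcript of its insertion locus. In 0 of the 7 marker lists with members above 1 CPM did at least 50% of these pass edgeR, but 3 lists were lower by camera and the gate followed the genotype. A different share of other cell types and an effect of the genotype therefore cannot be told apart for Il2rg, Emb, Igkc and Itgb3. The fall of Lyz2 (95% interval of the log2 fold change -1.32 to -0.977) lay beyond the 0.137 of large peritoneal macrophage markers. This argues against a changed share of these macrophages as its cause, while a part from other cell types stays open. Only LipaTg mice carried the Cre insertion in Lyz2 itself, and these counts cannot separate its effect from such a part.

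Lyz1 was higher while Lyz2 was lower. A fixed share of Lyz2 reads assigned to Lyz1 would have lowered both, while the lower 95% bound of the log2 fold change of Lyz1 was 1.24. Changed genes were more frequent within 20 Mb of Lyz2 (2 of 141 against 6 of 12700, exact one-sided Fisher p = 0.00321), but these 2 were Lyz1 and Lyz2 themselves, so the test decides nothing about linked alleles; without them 11 of 139 neighbours and 1276 of 12700 other genes had an unadjusted p under 0.05 (odds ratio 0.769, 95% interval 0.374 to 1.43), which argues against altered expression across the whole region. Transcripts of the Cre-bearing Lyz2 allele, or of its strain variants, may be assigned to Lyz1, since its gain was only 6.68% of the loss of Lyz2, and gene-level counts cannot exclude this. A response of Lyz1 to the genotype stays open as well. Linked alleles that alter only a few neighbours also stay open, since the interval of that odds ratio reached 1.43.

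The antigen presentation and cell cycle lists were higher in the deeper libraries. After thinning to equal totals both passed camera at the preset correlation (adjusted p = 2.44e-12 or less), against depth as the cause. B cells, which carry class II genes, would raise B cell markers, but the upper 95% bootstrap bound of that list's median was -0.237. This bound covers the spread over markers only, and the median was -0.1362 without Ctl5. Over all alternatives the median stayed negative, from -0.4037 to -0.1205. Small peritoneal macrophages and monocytes, which also carry class II genes, would raise their 12 markers by a similar amount, but the upper bound of their median was 0.208, below the lower bounds of 0.739 for class II genes and 0.566 for cell cycle genes. Over the alternatives the median of these markers ran from -0.1183 to 0.1989. They went both ways, 4 higher and 8 lower, with log2 fold changes of 0.71 for Fcgr4, 0.56 for Plac8 and -1.26 for Cd209a. A shift in part of these cells thus stays open. The antigen presentation and cell cycle lists both lost their call with an estimated correlation, and a response of the macrophages to the genotype, which was not tested, and the difference in gate stay open.

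Reads of Nnt, the mitochondrial transhydrogenase gene that is disrupted in the C57BL/6J substrain, were divided between 2 overlapping gene models in different proportions. The first model (ENSMUSG00000025453) held 15.9% to 25.9% of Nnt counts in the Ctl libraries, but 100% in LipaTg3 (exact 95% interval 99.4% to 100%), 78.9% in LipaTg4 (75.6% to 81.9%) and 41.3% in LipaTg5 (37.3% to 45.3%), intervals that cover counting error only. The sum of both models stayed at 28.2 ± 1.70 CPM in Ctl and 27.5 ± 0.286 CPM in LipaTg, a ratio of 0.974. An Nnt allele that segregates among these mice may explain the division. Uneven read assignment between the models would leave the sum unchanged as well, so the sum does not decide and both remain open. Emb is a neighbour of Nnt, and linked alleles could have lowered it. Among the other 80 tested genes within 20 Mb of Nnt the odds ratio for an unadjusted p under 0.05 was 0.997 (95% interval 0.414 to 2.08), which leaves the question open, and Emb was 5.82, 6.48 and 6.20 CPM in LipaTg3, LipaTg4 and LipaTg5, without a gradient that follows the share of Nnt.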
